A study of Mus musculus with 8 samples.

How the data were processed

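Total RNA from whole embryos and placentas at 15.5 days post coitum was labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. Mothers were on a BALB/c background and fathers on a C57BL/6J background, both carrying Robertsonian chromosomes that involve chromosome 12, per the labels. Embryos were run on the 430A chip and placentas on the U74A, U74B and U74C chips, with 1 array for each genotype and chip. The labels gave each sample's tissue, genotype and chip. Whether an array's RNA came from 1 animal or a pool, and whether the placental chips shared a target, is not given in the sources used here. The number of arrays limits the precision: no comparison has a replicate, and the 3 placental chips carry different probe sets and are not replicates of each other.

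The deposited values are signal intensity values per probe set on a linear scale, and MAS5 and GCOS are the tools named in the submitters' processing notes; their versions and settings are not given in the sources used here. The 2% trimmed mean of the deposited intensity values was close to 500 on each of the 8 arrays, between 500.1 and 500.3. The trimmed mean left out 2% of values at each end.

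Affymetrix control probe sets were left out of the gene comparisons. Of 22690 probe sets on 430A, 20393 had 1 gene symbol in the platform annotation, 691 several and 1606 none. For U74A the numbers were 10855, 396 and 1237 of 12488, for U74B 10603, 178 and 1696 of 12477, and for U74C 7739, 150 and 4045 of 11934. Probe sets with several symbols or none were left unnamed. Symbols were looked up in the RefSeq gene table of assembly GRCm38.p6, which matched 20364, 10839, 10572 and 7699 of the probe sets with 1 symbol on the 4 chips and changed 0 symbols; the table was used for names and chromosome numbers only.

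The arrays of a pair were scaled to a common trimmed mean, and the floor was set at 0.5 of it. A probe set was measured when at least 1 array of the pair reached the floor, and the dimmer value was raised to the floor before the ratio was taken, so that such a ratio is a bound. A gene was represented by its probe set with the highest mean signal. Genes and probe sets at least 2-fold apart were counted, and no test was run because each group had 1 array. Gene lists were described by the number of measured members on each side, the median log2 ratio and, with at least 5 measured members, the percentile of that median among 10000 random lists of the same size matched on chip and on 5 classes of mean signal. The percentile describes these arrays and is not a p-value. The share of chromosome 12 genes apart was set against random lists of other autosomal genes in the same way. Overlap between tissues was set against the product of the counts divided by the number of genes measured in both.

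The design, the 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per tissue and direction, the 10 genes of largest log2 ratio measured on both arrays and at least 2-fold apart, and the 5 brightest genes below the floor on 1 array whose other array reached 2 times the floor. Genes with a measured probe set pointing the other way were left out of those. It also took all genes of the Dlk1-Dio3 domain, genes at least 2-fold apart the same way in both tissues, up to 5 chromosome 12 genes per tissue and direction, the members of largest log2 ratio of each list described, Xist and the Y-linked genes. Basal keratins and a few further list members were named after their values were seen. The lists covered imprinted genes, embryonic organs, placental cell types, the decidua, blood, leukocytes, proliferation, stress and hypoxia.

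Alternatives were signals as deposited, centring on the median of probe sets above the floor, quantile normalization, lowess, floors at 0.25 of the trimmed mean, at 1 trimmed mean and no floor, the median over a gene's probe sets, rules of 1.5-fold and 3-fold, U74A alone, and chromosome 12 without the domain genes. The placenta without U74C was added after the data were seen.

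The steps were tested on simulated pairs of arrays with the real mean signals, random error with an SD of the log2 ratio of 0.2 on 430A, 0.3 on U74A, 0.35 on U74B and 0.55 on U74C, and 50 genes altered at each of 4 folds. For the embryo comparison, run on 7161 genes, the 2-fold rule called 0% of genes altered 1.5-fold, 48% of those altered 2-fold, 98% at 3-fold and 100% at 4-fold, with 0 unaltered genes called. For the placenta comparison, run on 10215 genes, it called 8%, 38%, 92% and 96%, with 175 unaltered genes called. Of 100 unaltered lists of 15 genes, 4 fell outside the central 95% in the embryo and 5 in the placenta, and of 50 lists shifted by 0.3, 50 and 36 were above the 97.5th percentile. The unaltered lists were drawn from the same simulated genes as the random lists, so a share near 5% was set by construction. Errors were independent between probe sets, so lists of genes that vary together were not tested. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.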

Results

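Gene expression was measured at 15.5 days post coitum in whole embryos and placentas of mice carrying both copies of chromosome 12 from the mother (matUPD12) or both from the father (patUPD12). Such uniparental disomy doubles or removes the active copy of each imprinted gene on the chromosome, so the comparison of matUPD12 with patUPD12 bears on which transcripts depend on the parent of origin. Mothers and fathers had different strain backgrounds, so parent of origin and strain cannot be told apart on chromosome 12. No sample had a chromosome 12 from each parent, so a difference can lie in either genotype. The 8 arrays covered 4 combinations of tissue and genotype. Each embryo genotype was run on 1 chip, the 430A, and each placenta genotype on 3 chips with different probe sets, the U74A, U74B and U74C. The labels do not state whether RNA was pooled from several animals, or whether the 3 placental chips of a genotype received the same RNA. There was 1 array per group and chip, so no spread between replicates could be measured and no p-value was computed. Differences are reported by size, as the ratio of matUPD12 to patUPD12, and a probe set counted as measured when at least 1 array of the pair reached the signal floor of about 250. The share of probe sets at or above that floor was 48.8% and 47.4% on the matUPD12 and patUPD12 embryo arrays, and lay between 42.7% and 50.9% on the 6 placenta arrays. Where the dimmer array was below the floor, the fold is given as "at least", computed against the floor.

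The Dlk1-Dio3 imprinted domain on chromosome 12, which checks the genotype labels, differed in the direction of the labels in embryo and placenta. Meg3 and Rian, noncoding RNAs transcribed from the maternal chromosome, were higher in matUPD12 embryo, and Dlk1, a paternally expressed transmembrane growth regulator, was lower in matUPD12 in both tissues. In the embryo the brightest Meg3 probe set gave a signal of 13003 in matUPD12 and 744 in patUPD12, a log2 ratio of 4.13. All 5 Meg3 probe sets were higher in matUPD12, by 3.85-fold to 47.4-fold, with 4 of these folds computed against the floor. The brightest Rian probe set read 1458 against 90.2, at least 5.83-fold higher, and a further 2 Rian probe sets were at least 4.42-fold and 1.23-fold higher. Embryonic Dlk1 read 3615 in matUPD12 and 20199 in patUPD12, a log2 ratio of -2.48 or a 5.59-fold difference.

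In the placenta Dlk1 on the U74A chip read 462 in matUPD12 and 4924 in patUPD12, a 10.7-fold difference with a log2 ratio of -3.41, and a U74C probe set for Dlk1 was at least 4.83-fold lower. Rtl1, a paternally expressed retrotransposon-derived gene needed for the fetal capillaries of the placenta, read 399 against 1051, a log2 ratio of -1.40. Dio3, the thyroid hormone inactivating deiodinase, read 76.8 against 334 on U74C, which bounds the difference only at 1.33-fold. Meg3 was represented by 9 placental probe sets, of which 4 were measured. On U74A, Meg3 read 1120 against 45.6, at least 4.48-fold higher, and 909 against 136, at least 3.64-fold higher. The brightest Meg3 probe set, on U74C, read 872 against 512, a log2 ratio of 0.77, and a U74B probe set for Meg3 pointed the other way at 193 against 358. Mirg, a maternally expressed microRNA host transcript, was at least 2.47-fold and 2.31-fold higher on 2 of its U74C probe sets and 1.29-fold higher on its brightest. The only placental Rian probe set was below the floor on both arrays, at 155 against 45.7.

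**Figure D1:**
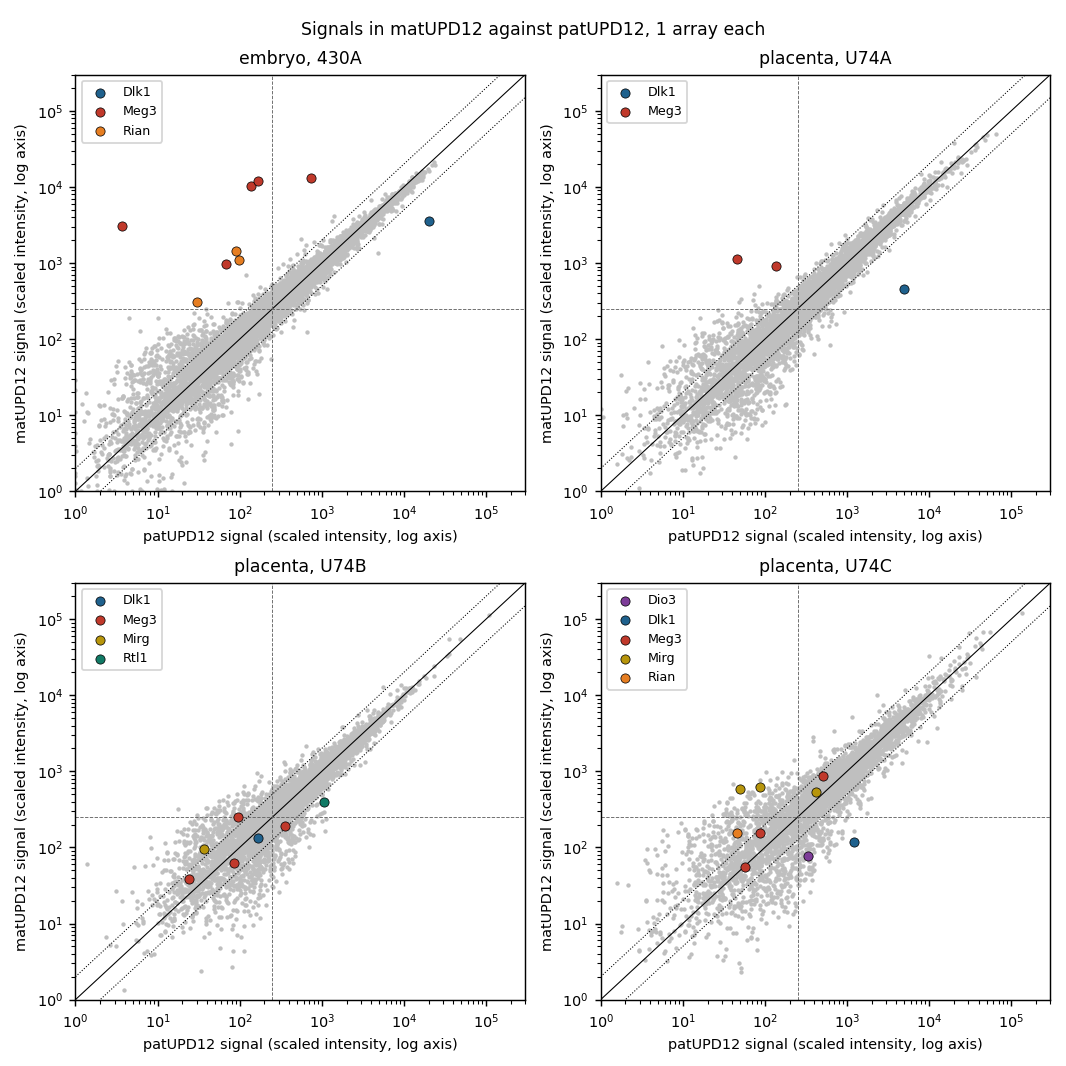
Each panel plots the matUPD12 signal against the patUPD12 signal of the same chip on log axes, in scaled intensity units, with 1 grey point per gene (values under 1 drawn at 1) and coloured points for the probe sets of the Dlk1-Dio3 domain. The solid line marks equal signals, the dotted lines a 2-fold difference and the dashed lines the floor; all 5 embryonic Meg3 probe sets lie far above the upper dotted line, embryonic Dlk1 lies far below the lower, and the grey cloud of the U74C panel is the widest.

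In the embryo, few genes differed by 2-fold, and those that were higher in matUPD12 were led, after Meg3 and Rian, by genes of the stratified epidermis. Loricrin (Lor), the main protein of the cornified envelope, was 3.72-fold higher, and the suprabasal keratins Krt10 and Krt1 were 2.89-fold and 2.65-fold higher. Genes lower in matUPD12 were led by Dlk1, by Serpina1c, a liver alpha-1 antitrypsin gene on chromosome 12, at 3.51-fold, and among genes measured on both arrays next by Mybph, a myosin binding protein of skeletal muscle, at 2.52-fold. Of 7259 measured genes, 19 were at least 2-fold higher and 14 at least 2-fold lower in matUPD12, and 97.1% differed by less than 1.5-fold. At the level of probe sets, 35 were higher and 23 lower among 11389 measured.

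Further epidermal genes among the most different were the calmodulin-like Calm4 (log2 ratio 1.54), the skin aspartic protease Asprv1 (1.53), the keratinocyte differentiation gene Krtdap (1.43) and the keratin Krt77 (1.27). Outside the skin, the liver and gut fatty acid binding protein Fabp1 was 2.74-fold higher in matUPD12, the surfactant protein gene Sftpc of the lung epithelium 2.47-fold and Bri3 2.66-fold. Among genes below the floor in patUPD12, Cysrt1 was at least 2.75-fold and the plasma copper carrier Cp at least 2.13-fold higher. On the lower side, muscle genes recurred: the acetylcholine receptor subunit Chrna1 had a log2 ratio of -1.05, and Ankrd2, a muscle ankyrin repeat gene, was below the floor in matUPD12 and at least 2.65-fold lower. Further genes lower in matUPD12 were Kdelr3 (-1.14), the condensin subunit Ncapg2 on chromosome 12 (-1.13), Dusp12 (-1.12), the fatty acid desaturase Scd1 (-1.08), the gluconeogenic enzyme Fbp1 (-1.07), Saal1 (-1.07) and Ccdc186 (at least 2.41-fold lower). The X inactivation RNA Xist read 4435 in matUPD12 and 3876 in patUPD12, and all 12 probe sets for Y-linked genes were below the floor on both embryo arrays.

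In the placenta, Dlk1 had the largest log2 ratio of the genes lower in matUPD12 and measured on both arrays, but the number of genes apart by 2-fold was far larger than in the embryo and came mostly from the U74C chip. Among genes measured on both arrays whose measured probe sets did not disagree in sign, those higher in matUPD12 were led by the zinc finger gene Zfp449 at 7.28-fold, Calr3 at 4.48-fold, the insulin receptor adaptor Grb14 at 4.42-fold and the aryl hydrocarbon receptor Ahr at 3.97-fold, all on U74C. Of 10662 measured genes, 201 were at least 2-fold higher and 198 at least 2-fold lower in matUPD12. Of these 399 genes, 46 were represented on U74A, 107 on U74B and 246 on U74C, and 69 had a measured probe set pointing the other way, as did 3 of the 33 embryonic genes. For scale, random error alone in the simulated placenta put 175 of 10015 unaltered genes at least 2-fold apart, so many of the 399 may reflect noise. Leaving U74C out, a choice made after the data were seen, gave 88 genes higher and 85 lower, and U74A alone gave 24 and 30.

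The 3 chips differed in how far the placental pair of arrays lay apart. Among measured probe sets, 1.22% were at least 2-fold apart on U74A, 2.86% on U74B and 9.28% on U74C, against 0.509% on the embryo's 430A. Of 30 values of bacterial control probe sets per chip, 26 lay below the floor on U74C and 29 on U74B. All 30 did on U74A and on 430A, so measured probe sets on U74C and U74B may include more background. Probe sets of the same gene varied around their mean log2 ratio with an SD of 0.29 on U74A, 0.33 on U74B and 0.55 on U74C. The log2 ratios of such probe sets correlated weakly across genes on every chip, at 0.27 on 430A, 0.17 on U74A, 0.09 on U74B and 0.07 on U74C. The 3'/5' signal ratio of the Gapdh control was 2.76 on the matUPD12 U74C array and 0.947 on the patUPD12 U74C array, and that of actin was 2.75 and 1.34. On the other 7 arrays the Gapdh ratio lay between 0.947 and 1.13.

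**Figure D2:**
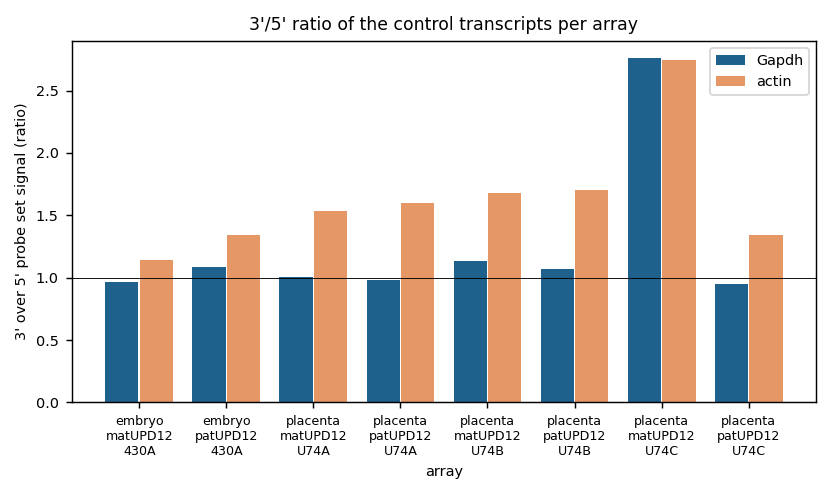
Bars give the ratio of the 3' to the 5' probe set signal for the control transcripts Gapdh and actin on each of the 8 arrays, with a line at a ratio of 1. The matUPD12 placenta U74C array stands apart with 2.76 for Gapdh and 2.75 for actin.

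Among placental genes represented on U74B, those higher in matUPD12 included the TGF-beta binding protein Vasn (log2 ratio 1.93), the splicing factor Snrpf (1.82), Fads6 (1.76) and glutaminyl cyclase Qpct, which was at least 3.82-fold higher. Genes lower there included 1700018A23Rik (-1.86), the mitochondrial ribosome recycling factor Mrrf (-1.84), the inositol phosphatase Ocrl (-1.81), the neuropeptide precursor Vgf at least 4.48-fold and the ferritin receptor Scara5 at least 4.34-fold. On U74C, the array pair with the differing 3'/5' controls, Ube2d1 (1.76), E430024I08Rik (1.57) and the Hedgehog pathway transcription factor Gli3 (1.53) were higher, with Exoc3l2, Cryga, Ifi27l2b and Slc15a5 at least 5.65-fold, 3.88-fold, 3.86-fold and 3.76-fold higher. Lower on U74C were Kpna6 (-2.62), Tpra1 (-2.11), Ptprj (-2.04), Cspp1 (-1.93), Synpo2 (-1.85) and Smpd3 (-1.85), and Stxbp4, Tex12 and Lyz1 were at least 4.88-fold, 4.03-fold and 3.75-fold lower. A second measured probe set of these genes, where there was 1, gave much smaller values, such as -0.08 for Kpna6, -0.28 for Tpra1, -0.19 for Ptprj and -0.13 for Cspp1. Xist probe sets were below the floor in the placenta, and of 9 Y-linked probe sets 8 were below it on both arrays, the exception being a Kdm5d probe set at 303 against 387.

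Chromosome 12 as a whole stood out in the embryo through the imprinted domain. Of 244 measured chromosome 12 genes, 2.05% were at least 2-fold apart, against 0.413% of 6776 genes on the other autosomes, and this share lay at the 99.9th percentile of 10000 random gene lists matched on chip and signal. The genes were Meg3, Rian, Dlk1, Serpina1c and Ncapg2. Without the domain genes the share was 0.830%, at the 84.6th percentile. In the placenta 5.84% of 394 chromosome 12 genes were at least 2-fold apart, against 3.67% of 9918 other autosomal genes, at the 96.9th percentile, and 5.40% at the 93.0th percentile without the domain genes. The median absolute log2 ratio of chromosome 12 genes was 0.13 in the embryo and 0.25 in the placenta, against 0.14 and 0.23 for the other autosomes.

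Outside the domain, 12 placental chromosome 12 genes were at least 2-fold higher and 9 at least 2-fold lower in matUPD12. The higher ones were led by Ahr and Ifi27l2b, followed by the neuropeptide receptor Vipr2 (at least 3.05-fold), the histone deacetylase Hdac9 (log2 ratio 1.48) and the sodium/calcium exchanger Slc8a3 (at least 2.54-fold), all on U74C. The lower ones were led by Prps1l3 (at least 3.44-fold), the potassium channel Kcnk10 (-1.73) and Plekhd1 (-1.58) on U74C, Nbas (at least 2.68-fold) on U74B and the matrix protein Smoc1 (-1.35) on U74A.

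Gene lists fixed before the data were examined separated embryonic tissues. Epidermal genes were higher in matUPD12 embryo and striated muscle genes were lower. All 12 measured epidermal genes were higher, with a median log2 ratio of 0.83, above every random list. The suprabasal genes Lor (1.90), Krt10 (1.53), Krtdap (1.43) and Krt1 (1.40) had the highest values. The basal keratins were at 0.83 (Krt5), 0.63 (Krt14) and 0.55 (Krt15), and the lowest values were bounds, 0.47 for Sprr1a and 0.18 for the basal regulator Trp63. All 27 measured genes of the skeletal muscle sarcomere were lower, with a median of -0.40, below every random list. Examples were Mybph (-1.34), the calcium release channel Ryr1 (-0.85), titin (Ttn, -0.85) and the slow troponin Tnni1 (-0.74). Of 9 myogenic regulators and myoblast genes 8 were lower (median -0.42), among them Chrna1, desmin (Des, -0.87) and myogenin (Myog, -0.51). Of 10 heart muscle genes 9 were lower (median -0.31), led by Myl3 (-0.87) and Myl7 (-0.66).

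Of 23 embryonic lists with at least 5 measured members, 12 had a median outside the central 95% of matched random lists. If genes varied independently, 1.15 would be outside by chance. Genes of a tissue can shift together between samples, and with 1 array per genotype that spread is unknown. Besides the epidermis, the higher lists were the pancreas, lung and gut epithelium (7 of 8 members higher, median 0.45, with Sftpc at 1.30 and Sftpb at 0.50), neuronal genes (17 of 19 higher, median 0.31, with the synaptic gene Snap25 at 0.70 and Stmn2 at 0.52) and cartilage (12 of 13 higher, median 0.27, with Matn4 and Col11a2 at 0.42). Besides muscle, the lower lists included fetal hepatocyte genes (17 of 20 lower, median -0.32), such as Itih3 (-0.95), Serpina1b (-0.73) and hemopexin (Hpx, -0.62), while Fabp1 of the same list was higher at 1.45. Yolk sac endoderm genes had a median of -0.22, with 8 of 9 lower, led by Apoc2 (-0.54) and Spink1 (-0.37), but 6 of these 9 genes, Apoc2 among them, are also in the hepatocyte list, so the 2 lists are not independent. Proliferation genes had a median of -0.19, with 20 of 24 lower, among them Ccne1 (-0.60), Mcm6 (-0.35) and Mki67 (-0.34). Imprinted genes on other chromosomes were mostly lower in both classes. Of the 13 paternally expressed genes measured, 10 were lower (median -0.25), with Magel2 at -0.73 and Peg3 at -0.42 and an exception in Nap1l5 at 0.55. Of the 13 maternally expressed genes measured, 10 were lower (median -0.18), with Dhcr7 at -0.30 and an exception in Osbpl5 at 0.44. With quantile or lowess scaling 2 of the 12 lists no longer stood outside the central 95% of lists scaled alike: with lowess the yolk sac median was -0.11, at the 9.51st percentile, and that of maternally expressed imprinted genes -0.10, at the 8.21st. The proliferation median was -0.12 with either scaling and stayed outside.

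The other 11 embryonic lists lay within the central 95%. These were bone (median 0.10), adipocyte differentiation (0.07), endothelium and pericyte (0.04), Notch pathway (0.03), leukocytes (0.02), labyrinth trophoblast and transport (-0.06), thyroid hormone responsive genes (-0.07), erythroid genes (-0.08), decidua and uterus (-0.09), immediate early and heat shock genes (-0.13) and hypoxia and glycolysis (-0.13). The endothelial median changed sign under another scaling of the signals, with a lowest value of -0.03. Within the adipocyte list Scd1 was lower at -1.08, and within the leukocyte list the macrophage gene Adgre1 was higher at 0.54.

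In the placenta, genes of the list for decidua and maternal uterus were higher in matUPD12, and those of the erythroid, hepatocyte and striated muscle lists were lower. The lists do not show which cells gave a signal, and the share of maternal tissue in each sample was not measured. The decidua and uterus list had a median of 0.52, above every random list, with 10 of 14 measured genes higher. It was led by the serine protease Htra3, at 12720 against 5561 (log2 ratio 1.19), and the decidual prolactin Prl8a2, at 30688 against 14039 (1.13, on U74C), followed by Hoxa11 and decorin (Dcn), both at 0.88, while Bmp2 of the same list was lower at -0.99. These are the brightest probe sets: the 3 measured for Htra3 ran from 0.22 to 1.19 and the 2 for Prl8a2 from 0.66 to 1.13. Without U74C the decidual median was 0.65. Erythroid genes had a median of -0.42, with 12 of 15 lower, among them Ermap (-0.97), the heme synthesis enzyme Alas2 (-0.95) and the embryonic globins Hba-x (-0.81) and Hbb-y (-0.75). Fetal hepatocyte genes had a median of -0.40, with 8 of 9 lower, led by albumin (Alb, -1.15) and Apoa1 (-0.80), and with Rbp4 higher at 0.73. Apoa1 and Rbp4 are also in the yolk sac endoderm list.

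Placental signals for skeletal muscle genes had a median of -0.35, with 11 of 13 lower, including Acta1 on U74A (-1.06) and Mylpf on U74C (-1.27). Those for heart muscle genes had a median of -0.58, with 6 of 7 lower, including Nppa (-0.73) and Myl4 (-0.67). Immediate early and heat shock genes had a median of 0.24, with 14 of 17 higher, including Fos (0.91), Ier3 (0.80) and Gadd45a (0.67). With all 3 chips, these were the 6 of 25 placental lists outside the central 95%, where 5% would be outside by chance if genes varied independently.

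The trophoblast lists lay within the central 95% of random lists. Giant cell and lactogen hormone genes had a median of 0.11, with 11 of 18 higher, including Ctsm (0.63) and Prl7b1 (0.60, on U74C). Spongiotrophoblast and glycogen cell genes had a median of -0.01 with 9 genes on each side, a sign that changed under another scaling, which gave up to 0.10. Their extremes were Aldh1a3 (-0.91) and Ceacam13 (0.55, on U74C). Labyrinth and transport genes had a median of -0.18, with 12 of 17 lower, including Slc38a2 (-0.92) and Ldoc1 (-0.79), both on U74C, and the X-linked homeobox gene Esx1 (-0.58). The remaining 16 placental lists had these medians: hypoxia and glycolysis 0.16, leukocytes 0.14, epidermis 0.05, endothelium and pericyte 0.01, thyroid hormone responsive genes -0.03, adipocyte differentiation -0.04, maternally expressed imprinted genes -0.06, Notch pathway -0.06, bone -0.06, neuronal genes -0.06, proliferation -0.07, pancreas, lung and gut epithelium -0.09, cartilage and myogenic regulators both -0.12, paternally expressed imprinted genes -0.15 and yolk sac endoderm -0.26. Without U74C the hypoxia and glycolysis median was 0.20, at the 99.0th percentile and so outside the central 95%. The thyroid hormone list was positive, at 0.08, under another scaling. Named members were the hypoxia gene Adm (0.89), the imprinted growth regulators Phlda2 (-1.04) and Cdkn1c (-0.60), and the imprinted gene Tnfrsf23 (0.83).

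**Figure D3:**
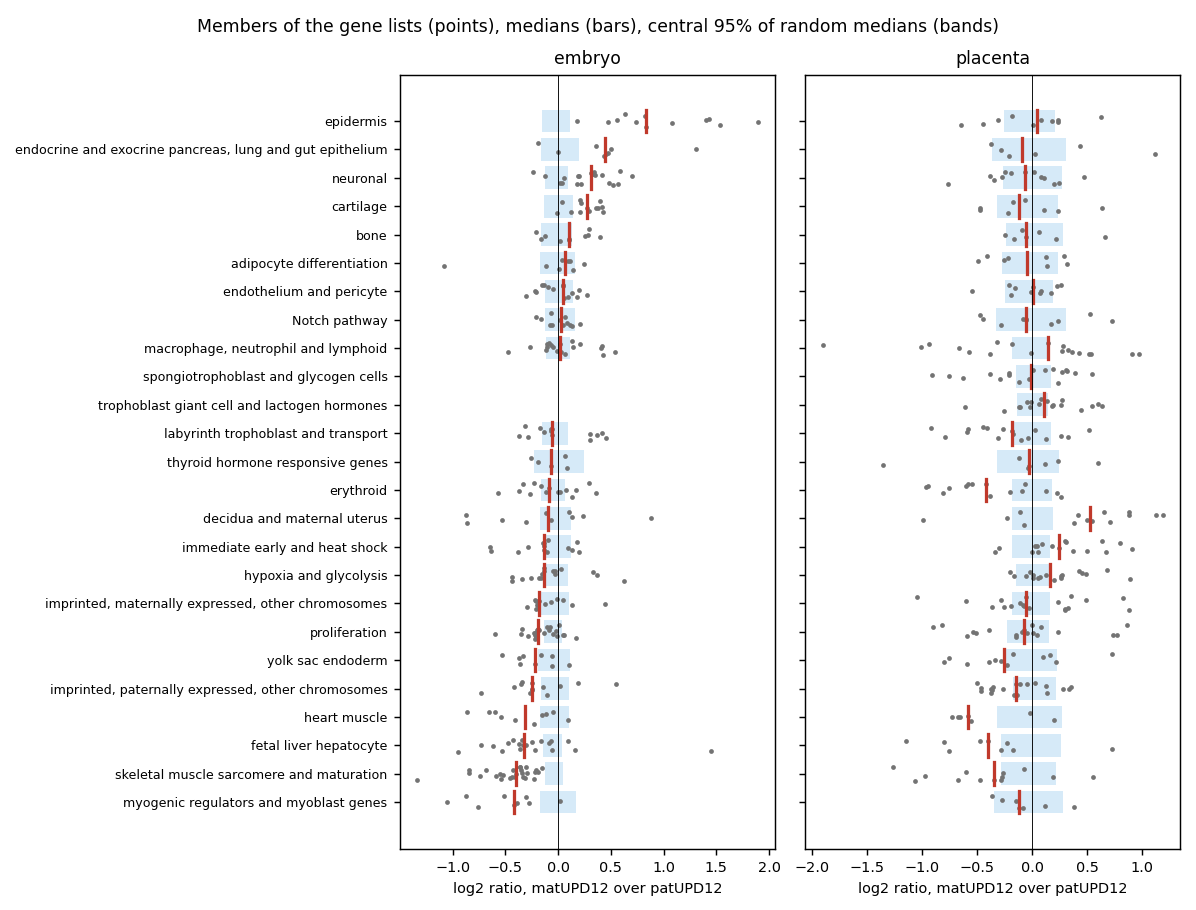
Points are the log2 ratios of matUPD12 over patUPD12 of the measured members of each gene list in embryo (left) and placenta (right), red bars are list medians, and blue bands hold the central 95% of medians of matched random lists. The embryonic epidermis median of 0.83 and the placental decidua median of 0.52 lie to the right of their bands, and the embryonic skeletal muscle median of -0.40 lies to the left.

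Across tissues, 5846 genes were measured in both embryo and placenta. Dlk1 was at least 2-fold lower in matUPD12 in both, where independent lists would share 0.137 genes, and Krt77 was at least 2-fold higher in both, where 0.151 would be shared. Krt77 had a log2 ratio of 1.27 in the embryo and was at least 2.04-fold higher in the placenta. At the same floor 1 gene, Ccdc186, was 2-fold lower in the embryo and 2-fold higher in the placenta, where 0.128 would be by chance. With the floor raised to 1 trimmed mean 0 genes were higher in both.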

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

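Of the tests in this part, the one of bright U74C probe sets was chosen before its result was seen, and the others only after.

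Ccdc186 was at least 2-fold apart in opposite directions in the 2 tissues, with a log2 ratio of -1.27 in the embryo and 1.29 in the placenta; the difference between tissues was not tested. Probe sets without a gene name were used in no gene comparison. The largest absolute log2 ratio among those at least 2-fold apart was 1.38 on U74A, 1.60 on U74B and 3.16 on U74C, all higher in matUPD12, and U74C held 141 of these probe sets. The 3'/5' ratios of the control transcripts on the matUPD12 placenta U74C array, 2.76 for Gapdh and 2.75 for actin, lay outside the range of the other 7 arrays, which was 0.947 to 1.13 for Gapdh and 1.14 to 1.70 for actin.

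The placental pair on U74C lay further apart than any other pair. Among probe sets with a mean signal of at least 1000, the SD of the log2 ratio on U74C was 1.74 times the largest of the other chips (0.55 against 0.31). Dim signals stay open all the same, because a scaled signal of 1000 need not mean the same brightness on each chip. The BioB control, for example, read 1212 and 935 on the matUPD12 and patUPD12 U74C arrays, and 300 and 427 on the U74A arrays. A further check took the 145 genes at least 2-fold apart on U74C and measured on U74A or U74B. Only 1 was also 2-fold apart there with the same sign. In the simulated placenta, where a gene's probe sets shared each change, the 2-fold rule called 38% of genes altered 2-fold. This argues against genotype differences of 2-fold in most of these 145 genes. Smaller differences, and genes seen only on U74C, stay open. Of the 145 genes, 57.9% (exact 95% interval 49.5% to 66.1%) had the same sign on the other chips. The same check of 20 U74B genes on U74A gave 50% (27.2% to 72.8%), too few genes to show whether the agreement on U74C was unusual. Degraded or 3'-biased target on the matUPD12 array remains a candidate explanation, since its Gapdh ratio of 2.76 was over 2 times the highest of the others, but with 1 array it was not tested further.

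Chromosome 12 genes outside the imprinted domain leaned the same way in embryo and placenta. Across 193 genes, which are not independent replicates, the log2 ratios correlated with a Pearson's r of 0.21 (Spearman's rho 0.17), at the 99.3rd percentile of matched random lists, and the highest r of the other 19 chromosomes was 0.15. Without the Serpina genes, a cluster of related neighbours, r was 0.14 at the 93.8th percentile, so the lean rests in part on Serpina1c, Serpina1b and Serpina6 and chance cannot be told apart from a shared difference in the rest. Mismatch of the probes to the maternal strain would mainly give lower signals in matUPD12, but of 12 genes with log2 ratios of at least 0.32 the same way in both tissues 33.3% were lower (exact 95% interval 9.92% to 65.1%), too few to decide. Strain alleles that alter expression and parent-of-origin effects, both of which the cross confounds, stay open and were not tested.

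The matUPD12 embryo had higher epidermal and lower muscle signals. The Gapdh and actin 3'/5' ratios differed between the embryo arrays by at most 0.23 on the log2 scale, less than either list median. These control transcripts cannot bound the effect of a 3' bias on other probe sets, so it stays open. A larger share of skin in the RNA stays open too. The basal keratins Krt5, Krt14 and Krt15 were higher by at least 0.55, more than the SD of 0.22 between probe sets of a gene, which does not measure spread between embryos. Basal Trp63, below the floor in patUPD12, gave only a bound of 0.18. The basal keratins belong to the epidermis list itself and were picked after its values were seen, so they are no separate evidence. The suprabasal genes Lor, Krt10, Krtdap and Krt1 were higher still, with a gap of 0.57. These had the highest values of the list and were picked after the values were seen, so the gap is no separate evidence. Sprr1a of the same list, a bound, lay below the basal keratins. A difference in stage and an effect of the genotype on skin and muscle stay open and, with 1 embryo sample per genotype, were not tested.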

How the results depend on the processing

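The setting without U74C was chosen after the data were seen. No paired analysis was possible because each group had 1 sample per chip and no test was run. The named genes checked were those taken by size, from chromosome 12, from the Dlk1-Dio3 domain or as shared between tissues. Genes named only as list members, such as Htra3 and Alb, were not checked. No checked gene at least 2-fold apart and no list median outside the central 95% of random lists changed sign. By contrast, 18 of the 48 list medians, all inside the central 95%, did under at least 1 alternative (6 in the embryo and 12 in the placenta, among them placental Notch, leukocyte and adipocyte genes). The 4 scalings (as deposited, median centring, quantile, lowess) each left all 70 values they gave within the limits used: 1.5 times for counts, the SD of members for list medians, the SD between probe sets of a gene for single genes and the exact binomial 95% interval for shares. The first 2 scalings could change little, because the deposited trimmed means were nearly equal and the median log2 ratios per chip lay between -0.01 and 0.02. The limit for list medians is wide: over the 4 scalings 4 of 48 medians moved by more than 0.1, at most by 0.12 (bone in the embryo), and 3 that lay inside the central 95% changed sign (endothelium in the embryo, spongiotrophoblast and thyroid in the placenta). Yolk sac endoderm and maternally expressed imprinted genes in the embryo stayed within that limit, yet moved inside the central 95% with quantile or lowess scaling. Of 507 values for 61 pairs of checked gene and tissue outside the domain, 77 moved by more than the SD between probe sets of a gene and 33 were under 2-fold. Signal over background left 11237 of 22626 probe sets on 430A and 5961 of 11868 on U74C below the floor on both arrays and so without a ratio. The cause of the shifts was not tested, except where a rule sets them by construction.

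Counts are given as higher and lower in matUPD12. With the floor at 0.25 of the trimmed mean there were 73 and 39 embryonic probe sets, 33 and 22 embryonic genes, 1123 and 1097 placental probe sets, 446 and 442 placental genes and 2 genes lower in both tissues. The log2 ratio of Rian in the embryo was 3.54 and that of placental Dio3 -1.42, the embryonic thyroid list had a median of 0.10, and 8.96% of placental chromosome 12 genes were apart. With the floor at 1 trimmed mean the counts were 19 and 10, 11 and 5, 118 and 149, 73 and 80, and 0 genes were higher in both tissues. Rian was at 1.54, the placental myogenic list at 0.38 and the placental chromosome 12 share at 2.36%. With no floor the counts were 1190 and 748, 501 and 314, 4240 and 4118, 1233 and 1339, and 52 and 34 in both tissues. Rian was at 4.01 and placental Dio3 at -2.12, the embryonic thyroid list at 0.13, the placental epidermis list at -0.36 and the placental adipocyte list at -0.43, and the chromosome 12 shares were 8.07% in embryo and 18.3% in placenta.

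With the median over a gene's probe sets, embryonic Rian was at 2.14, placental Mirg at 1.21 and Dlk1 at -2.84, and 2 genes were higher in both tissues. By construction, the 1.5-fold rule raised the counts to 216 and 154, 119 and 95, 1529 and 1519, 775 and 768, and 11 and 6 in both tissues, with chromosome 12 shares of 4.92% and 17.3%. The 3-fold rule lowered them to 11 and 3, 3 and 2, 51 and 70, 23 and 34, and 0 higher in both tissues, with a placental chromosome 12 share of 1.52%. U74A alone gave 30 and 42 placental probe sets, 24 and 30 genes, Meg3 at 2.16 and a chromosome 12 share of 3.40%. Without U74C there were 139 and 131 probe sets, 88 and 85 genes, Meg3 at 2.16, and 2 genes higher in both tissues.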

Other observations

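On chromosome 12 outside the Dlk1-Dio3 domain, the 12 genes with log2 ratios of at least 0.32 the same way in embryo and placenta, a limit chosen after the data were seen, were 4 lower and 8 higher in matUPD12, and 0 were that far apart in opposite directions. On the other chromosomes 54.8% of 314 such genes pointed the same way. Lower in both tissues were the antitrypsin genes Serpina1c (log2 ratio -1.81 in embryo, -0.76 in placenta) and Serpina1b (-0.73 and -0.47), Cdca4 (-0.66 and -0.37) and the chaperone Hsp90aa1 (-0.35 and -0.37). Higher in both were the corticosteroid binding globulin gene Serpina6 (0.80 and 0.43), the LIM domain gene Crip1 (0.43 and 1.32), the sphingosine phosphate phosphatase Sgpp1 (0.51 and 0.51), Entpd5 (0.39 and 0.70), Tmem30b (0.37 and 0.76), Itgb1bp1 (0.37 and 0.60), Lratd1 (0.35 and 0.53) and Susd6 (0.34 and 0.40).

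Of 19 measured placental leukocyte genes 10 were higher and 9 lower in matUPD12, and no cell type within the list was tested. The members of largest log2 ratio were on both sides. The lysozymes Lyz1 (-1.91, a bound) and Lyz2 (-1.01) and the protease Ctss (-0.94) were lower, and S100a8 (0.97) and the granzyme Gzmc (0.91) were higher.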
